A study of Mus musculus with 37 samples.

How the data were processed

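Messenger RNA was sequenced from mouse neurons in 37 libraries, which the labels place in 4 experiments. The nuclei experiment compared hippocampal neuronal nuclei of C57/Bl6 mice that were wild type (WT, n = 4) or CamKIIaCreERt2;Tet2 conditional knockout (cKO, n = 3). The first knockdown compared primary neuron cultures of embryonic day 17 given a lentivirus against luciferase (shLuciferase, n = 6) with cultures given a lentivirus labelled shTet2 (n = 6). The second knockdown compared cultured neurons labelled shLuc (n = 6) with cultured neurons labelled Tet2 knockdown (n = 6). Its column names carry the mark 3d, which those of the first knockdown lack, and no meaning was assigned to it here. The overexpression experiment compared cultured neurons labelled synGFP (n = 3) with neurons labelled Tet2 overexpression (n = 3). Per the labels' protocols, RNA of the nuclei and of the first knockdown was extracted with TRIzol, RNA of the other experiments with RNeasy, and all libraries were polyA-selected, strand-specific and read in pairs.

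The authors deposited 1 table per experiment, each with 24411 genes named by symbol. Per the submitters' processing notes, STAR, RSEM and DESeq2 were used on build mm10, and their versions, roles and gene annotation were not stated. The deposited signal per library was a normalized count: in each library the values were whole multiples of 1 step (100% within a tolerance of 0.01 reads), as gene counts divided by 1 size factor give. The deposited baseMean was the mean signal over the libraries of a table. The deposited log2 fold change and its standard error, the deposited Wald score and the deposited p-value and adjusted p-value were DESeq2 output, per the file headers. The authors' log2 fold change ran control over treated in the nuclei table and treated over control in the other tables. It was turned to treated over control here. Which strand setting was used for counting was not stated, so genes overlapping on opposite strands are reported as uncertain.

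Samples were assigned to columns by group name. In the second knockdown and the overexpression experiment the numbers in the column names differed from those in the sample titles, so columns were mapped to groups only, and a library of these experiments is named here by the number in its column. All 37 libraries were used. Reads per library were recovered as the deposited value divided by the step. They came to 6377244 to 12181847 in WT nuclei, 9638526 to 14882249 in cKO nuclei, 3029938 to 43788798 in shLuciferase cultures, 2709421 to 22091432 in cultures labelled shTet2, 4785087 to 22781534 in shLuc cultures, 6318167 to 20047667 in Tet2 knockdown cultures, 16988077 to 48321564 in GFP cultures and 66684922 to 73220675 in Tet2 overexpression cultures.

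The design fixed before the data were examined named edgeR for counts and limma-trend for normalized values. Since the tables held normalized values, limma 3.58.1 in R 4.3.3 was used. Values were transformed as log2(value + 1), genes with a mean of 0.5 or more were kept, and the empirical Bayes fit used a trend on mean level. Fold changes on this scale understate those of low genes. Genes were called at a Benjamini-Hochberg adjusted p (false discovery rate) of 0.05, all tests being two-sided. Only the libraries of 1 experiment entered its fit. Tet2 itself was also compared by an exact two-sided permutation test of the group means. In the text, SD is the spread over libraries, SE the standard error of a fold change, and p adjusted over all genes of limma unless another is named.

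The 24 gene lists, the rule for naming genes and part of the alternatives were also written before the data were examined. Other alternatives, among them TMM factors, library totals and the correction for GC content and length, were chosen later, as named below. Of the lists, 23 could be tested, and the list of mitochondrially encoded genes had 0 of its 15 members in the tables. A list was compared with all other genes by camera in limma with a preset correlation between genes of 0.01, adjusted over the lists of an experiment. The test was repeated with a correlation estimated from the data and with fry, which asks whether a list moves on balance and compares it with no other genes. Within a list, members were also adjusted over the list alone. Genes named were the Tet genes and, among called genes with a mean log2 CPM of 1 or more, the 8 with the largest rise, the 8 with the largest fall, the 4 with the smallest p in each direction and up to 4 per list. If fewer than 2 genes of a list were called, the 2 with the smallest p were named as values. For genes shared between experiments the 8 largest per direction for the knockdowns and the 6 largest otherwise were eligible, and for the difference between knockdowns the 4 with the smallest p per direction. Names were taken from the top of each.

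The difference between the knockdowns was tested in 1 limma fit of both tables with a term for each table and each treatment. Overlaps of called genes were set beside the number expected of independent lists, from each experiment's calls among the genes tested in both. No control library was shared between experiments. Symbols were matched to GENCODE vM21 (build GRCm38, the same as mm10) for position, transcript length, GC content and 3' UTR, and 23376 of the 24411 symbols (95.8%) matched. Coordinates are 1-based. Every 7-base word (7-mer) present in at least 50 of the 3' UTRs of genes with a mean of 32 or more was tested for its relation to the fold change. The length and GC content of the 3' UTR were covariates. Words were ranked in a fit across genes of the fold change divided by its SE, and coefficients came from a fit of the fold change itself. The SE of a coefficient is a spread over genes, which are not independent replicates, and not over libraries. Site genes were also compared with genes matched on those covariates, with intervals from 1000 bootstrap draws over genes. A site score per library was the coefficient of a 7-mer on each library's log2 deviations from the mean of its experiment. The 7-mer scan was chosen after the data were seen. For 2 lists of the overexpression experiment the mean log2 level relative to all genes was compared between groups, with a 95% interval from the t distribution over libraries, also after the data were seen.

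The alternatives were edgeR 4.0.16 on the recovered reads with TMM, RLE or upper-quartile factors, DESeq2 1.42.0, limma-voom with quality weights, other filters and a pseudocount of 0.1, library totals as the scaling, a correction for GC content and transcript length, the replicate number as a block, each library left out in turn, other thresholds and the authors' own adjusted p. Each step was tested on simulated data drawn from the means and library sizes of each experiment. With 100 genes changed by 1 on the log2 scale, limma recovered 20% in the nuclei, 46% in the first knockdown, 97% in the second and 0% in the overexpression experiment. With 100 genes changed by 2 it recovered 73%, 77%, 100% and 11% in the same order. Of its calls in those simulations, 7.92%, 5.38%, 2.96% and 0% were false. DESeq2 gave 40.5%, 18.2%, 9.17% and 73.9% false calls there, so its counts and those of the authors are given as alternatives. Precision for single genes therefore differed between experiments. A gene not called in the nuclei or with overexpression may have changed by less than the depth and number of libraries could show. Far fewer genes were changed in the simulations than were called in the second knockdown and with overexpression, so their rates may not carry over there.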

Results

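Polyadenylated RNA was measured in 37 libraries of mouse neurons in 4 experiments meant to lower or raise the methylcytosine dioxygenase Tet2. Neuronal nuclei of the hippocampus were taken from 4 WT and 3 Tet2 cKO mice. The first knockdown had 6 shLuciferase libraries and 6 libraries labelled shTet2, the second had 6 shLuc and 6 Tet2 knockdown libraries, and the overexpression experiment had 3 GFP and 3 Tet2 libraries. Depth ran from 2709421 to 43788798 reads per library in the first knockdown, from 4785087 to 22781534 in the second and from 6377244 to 14882249 in the nuclei. It differed by group in the overexpression experiment, where the Tet2 libraries held 66684922 to 73220675 reads and the GFP libraries 16988077 to 48321564. Despite this, fewer genes had a read in the Tet2 libraries (16457 to 18371) than in the GFP libraries (18540 to 21194). The 45S ribosomal precursor Rn45s took 18.1% to 27.1% of the reads in the nuclei, 11.97% to 16.2% in the second knockdown and 1.38% to 4.17% in the first. In the overexpression experiment it took 0.0607% to 0.411% in GFP and 0.00452% to 0.00662% in Tet2 libraries. No library was a copy of another of its group: the smallest chi-square per gene between replicates was 5.67. Replicates of the overexpression experiment were the least alike across genes, with a Spearman correlation of 0.755 to 0.839 within groups, against 0.961 to 0.990 in the second knockdown.

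Tet2 oxidizes methylated cytosine and lies on chromosome 3 (133463679 to 133545139, minus strand, GENCODE vM21 on mm10). In the nuclei, which asked what loss of Tet2 in CamKIIa-expressing neurons of the living hippocampus changes, Tet2 stood at 986 ± 73.9 normalized counts in WT (SD, n = 4) and 639 ± 201 in cKO (n = 3). All 3 cKO nuclei libraries (484, 566 and 866) lay below the WT range of 893 to 1070. The exact permutation p was 0.0286, the smallest that 4 against 3 libraries can give, while over all genes the log2 fold change of −0.67 (SE 0.24) had an adjusted p of 0.632. A deletion can leave reads from the exons outside the deleted part, and the labels do not say which exons were removed. In the first knockdown Tet2 was not lower in the libraries labelled shTet2, at 504 ± 149 (n = 6) against 461 ± 190 in shLuciferase (n = 6). Their values of 315 to 672 lay within the shLuciferase range of 167 to 720, with a log2 fold change of 0.21 (SE 0.29, 95% confidence interval −0.39 to 0.80) and an exact permutation p of 0.610. In the second knockdown Tet2 fell from 459 ± 74.7 to 175 ± 87.6 (n = 6 each), a log2 fold change of −1.51 (SE 0.24, adjusted p 1.1e-04, exact permutation p 0.00216), and every knockdown library (88.2 to 296) lay below every control (348 to 528). In the overexpression experiment the 3 Tet2 libraries (2815, 3061 and 5592) lay above the 3 GFP libraries (876, 1905 and 2391). Their log2 fold change of 1.20 (SE 0.48, and 0.77 without GFP 4 to 1.49 without GFP 6) had an adjusted p of 0.116. The exact permutation p of 0.1 is the smallest that 3 against 3 libraries can give. The normalized counts summed to 22488800 to 52712900 in GFP and 52390700 to 68642300 in Tet2 libraries, so the size of this change depends on the scaling.

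The paralogs of Tet2 were read in the same libraries. Tet3 rose by 0.58 (SE 0.11, adjusted p 8.3e-04) and Tet1 changed by −0.61 (SE 0.16, adjusted p 0.00787) on the log2 scale in the second knockdown. Tet3 rose by 1.59 (SE 0.45, adjusted p 0.0343) with overexpression, a call that was lost with upper-quartile factors, with library totals and without GFP 4 or 5 or any 1 of the Tet2 libraries. Neither paralog was called in the first knockdown (Tet1 −0.52, Tet3 0.33) or in the nuclei (Tet1 −0.51, Tet3 −0.75).

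**Figure D1:**
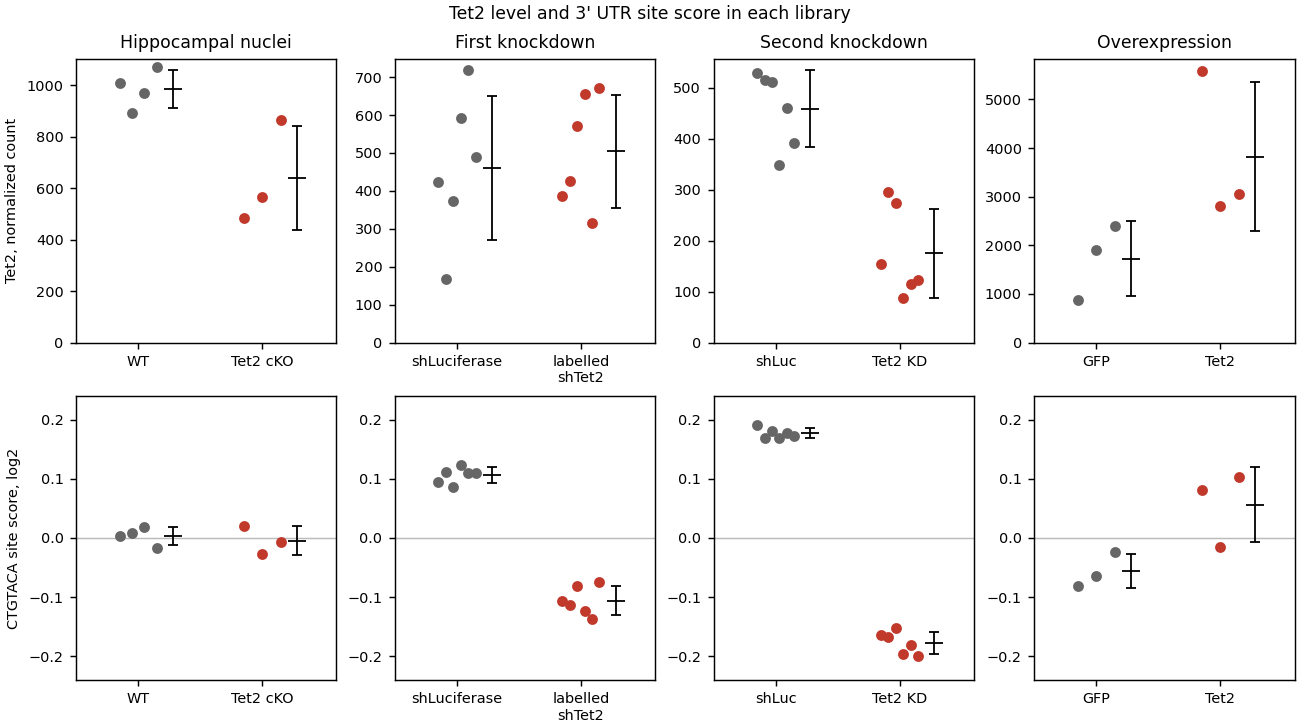
Upper panels show the normalized count of Tet2 and lower panels the log2 site score of the 3' UTR word CTGTACA in each library (points), with mean and SD (bars). Tet2 of the libraries labelled shTet2 (315 to 672) lies among the shLuciferase values, whereas their site scores (−0.138 to −0.0748) all lie below those of shLuciferase (0.0869 to 0.124).

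In the hippocampal nuclei no gene passed the adjusted threshold. limma called 0 of 18780 genes, with 1309 at an unadjusted p under 0.05 where 939 are due to chance, and edgeR called 0, with 1042. DESeq2 called 91 and the authors' own adjusted p called 96 (33 higher and 63 lower in cKO). The values with the smallest p in their lists included Zbtb20, a repressor that shapes CA1 neurons, at 1841 ± 245 in WT and 839 ± 239 in cKO (log2 fold change −1.16, SE 0.23, adjusted p 0.529). Wfs1, a CA1 marker of the endoplasmic reticulum, stood at 2775 ± 251 and 4536 ± 765 (0.70, SE 0.19, adjusted p 0.569). The teneurin Tenm1 stood at 282 ± 102 and 648 ± 102 (1.28, SE 0.33) and the auxiliary protein of AMPA receptors Cacng5 at 379 ± 127 and 858 ± 200.1 (1.23, SE 0.31), each with an adjusted p of 0.529. Adjusted over their list alone, Zbtb20 fell (0.00182) and Wfs1 (0.0232) and Cacng5 (0.0300) rose, the only 3 genes to pass so in any list. With DESeq2, whose false calls in simulated nuclei came to 40.5%, Zbtb20 and Wfs1 passed and Tenm1 and Cacng5 did not.

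In the cKO nuclei 7 lists passed upwards with the preset correlation, and none with an estimated one. Of 74 cytosolic ribosomal protein genes, 70 had a positive fold change with a median of 0.44 on the log2 scale (Rpl29 1.55, Rps23 0.94), and the list passed the test at an adjusted p of 4.4e-22 (0.370 with an estimated correlation). Of 73 nuclear-encoded respiratory chain genes, 71 were positive with a median of 0.37 (Ndufa3 0.99, Cox4i1 0.51, adjusted p 1.3e-15). Neuropeptides (26 of 31 positive, Sst 0.79 and Cck 0.63, adjusted p 3.2e-05), genes of GABA receptors and GABAergic neurons (30 of 38, adjusted p 1.6e-04), cell adhesion at synapses (43 of 59, adjusted p 1.6e-04), the integrated stress and unfolded protein response (35 of 44, adjusted p 3.5e-04) and cholesterol synthesis (20 of 25, adjusted p 0.0447) passed in the same direction. On the cell adhesion list WT nuclei 6 stood apart, with a mean log2 level of 9.78 against 9.87 to 9.88 in the other WT libraries, and the list also passed upwards without it. With an estimated correlation all 7 calls were lost (adjusted p 0.370 for each), and fry called 0 lists. The correlation estimated between genes was 0.248 for the ribosomal and 0.539 for the respiratory list. Longer transcripts stood lower in cKO, with a Spearman correlation of −0.25 between length and fold change across genes, which are not independent replicates. Among the 16 lists that did not pass, immediate early genes and vascular and meningeal markers came nearest (adjusted p 0.106 for each).

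The first knockdown asked what a Tet2 hairpin changes in cultured neurons, and its direction is that of the libraries labelled shTet2, whose Tet2 was not lower. Of 18315 genes, 354 were called, 120 higher and 234 lower, and 331 of these were also called by edgeR, which called 382. The median size of the called changes was 0.97 on the log2 scale. Without shLuciferase 3 the count was 222 and without shTet2 4 it was 234, while DESeq2 called 888 and voom 900. Rises included Scn3b, an accessory subunit of sodium channels, from 446 ± 169.8 to 2043 ± 550.4 normalized counts (log2 fold change 2.23, SE 0.24, adjusted p 2.0e-05, n = 6 each), and the small GTPase Diras2 (1.38, SE 0.19). Dhps, which modifies a translation factor, rose by 1.74 (SE 0.36), Cmtm6, a membrane protein, by 1.63 (SE 0.31) and the noncoding Ftx by 1.81 (SE 0.36). Nrep, a protein of regenerating neurons, rose from 4300 ± 702 to 8195 ± 809. The noncoding genes Ino80dos (2.83, SE 0.67) and Chd3os (1.50, SE 0.15) overlap coding genes on the other strand and remain uncertain.

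The fall with the smallest p was in Slc25a22, the carrier that brings glutamate into mitochondria (chromosome 7, 141429744 to 141437892), from 2917 ± 562 to 481 ± 72.1 (log2 fold change −2.59, SE 0.16, adjusted p 3.1e-09). Zwint, a kinetochore protein also present in neurons, changed by −1.76 (SE 0.14), the vesicle fusion clamp Cplx1 by −1.63 (SE 0.15) and the cell cycle exit factor Cend1 by −1.28 (SE 0.13). The calcium sensor of vesicle release Syt2 changed by −3.83 (SE 0.89), the neuropeptide gene Cort by −2.28 (SE 0.47), the receptor kinase Kit by −2.12 (SE 0.35) and the nuclear receptor Nr4a2 by −2.07 (SE 0.39). Acan, a proteoglycan of perineuronal nets, changed by −2.09 (adjusted p 0.0449, but 0.0698 with edgeR). All genes named in this paragraph except Acan had no overlap between the 6 libraries labelled shTet2 and the 6 shLuciferase libraries.

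Activity-regulated genes fell as a group in the libraries labelled shTet2. Of 32 immediate early genes 0 rose, 5 fell (Nr4a1 −1.66, Fos −1.45, Fosl2 −1.25, Nr4a2 −2.07 and Nr4a3 −1.63) and 27 did not pass. Adjusted over the list alone 1 rose and 7 fell. Their median was −0.70, with an adjusted p of 5.5e-09 and of 0.0315 with an estimated correlation, the 1 list call of this experiment that held with it. Of 50 genes of synaptic plasticity and memory, 1 rose and 4 fell (Reln −1.44, Ntrk2 −0.69 and Prkaca −0.76 among them), or 1 and 6 adjusted over the list alone. Of 38 genes of GABA receptors and GABAergic neurons, 1 rose and 3 fell (Reln, Nlgn2 −0.99 and Gabra5 −1.18), or 1 and 5 over the list alone. Of 54 synaptic vesicle genes, 2 rose (Napb 1.03 and Syt5 0.73) and 5 fell, with Rab3b at −1.09 besides Cplx1, or 4 and 7 over the list alone. These 3 lists passed downwards (adjusted p 1.5e-05, 3.0e-06 and 2.5e-04), and with an estimated correlation each call was lost (adjusted p 0.0638, 0.0561 and 0.0638). On the vesicle list shLuciferase 4 stood apart, with a mean log2 level of 9.30 against 9.46 to 9.55 in the other controls.

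Another 10 lists passed downwards there, with few members called, and each call was lost with an estimated correlation. Of 31 neuropeptide genes, 1 rose (Scg5 0.74) and 3 fell (Tac1 −1.16, Cort and Cpe −0.72), or 1 and 4 adjusted over the list alone (list adjusted p 1.9e-06, but 0.101 with an estimated correlation). shLuciferase 2 stood apart on this list, with a mean log2 level of 8.89 against 8.02 to 8.29 in the other controls, and the list also passed downwards without it. Of 29 astrocyte markers 3 fell (Slc4a4 −0.83, Clu −0.69 and Aldoc −0.62), and 10 over the list alone (adjusted p 3.6e-08, but 0.0638 with an estimated correlation). Of 73 respiratory chain genes 5 fell (Ndufb8 −0.95, Ndufa2 −0.82, Uqcrfs1 −0.52 and Uqcr10 −0.64 among them), and 7 over the list alone (adjusted p 1.9e-06, but 0.313 with an estimated correlation). Glutamate receptors with 0 of 39 called, axon guidance and dendrite growth with 1 of 67 lower (Stmn1 −0.75) and cell adhesion at synapses with 2 of 59 lower (Tenm3 −1.64 and Nlgn2) passed as lists (adjusted p 0.00924, 0.00370 and 9.8e-04), and each call was lost with an estimated correlation (adjusted p 0.0561, 0.0561 and 0.191). Hippocampal excitatory neuron markers (3 of 32 lower, Dcn −1.39, Calb1 −0.84 and Etv1 −1.13), vascular and meningeal markers (1 of 30 lower), neural progenitor and proliferation genes (Nes higher at 1.41, Hmgb2 lower at −0.79, of 43) and oligodendrocyte markers (0 of 29 called) passed at adjusted p of 0.0216, 0.00924, 0.0125 and 0.0370. With an estimated correlation these 4 calls were lost (adjusted p 0.183, 0.127, 0.183 and 0.312).

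Antiviral genes were the only list to pass upwards in the first knockdown. Of 45 interferon and antiviral genes, 2 rose (the peptide transporter Tap1 1.79 and Ifit3 3.79), 3 adjusted over the list alone, and the median was 0.75 (adjusted p 0.00455, but 0.151 with an estimated correlation). shLuciferase 4 stood apart on this list, with a mean log2 level of 2.51 against 3.12 to 3.48 in the other controls, and without it the list also passed upwards but Tap1 and Ifit3 were no longer called. Ifit3 had an adjusted p of 0.0441 with limma and 0.102 with edgeR, at 7.73 ± 9.27 and 59.3 ± 30.2 normalized counts. Lists that did not pass were DNA methylation and hydroxymethylation machinery (Idh2 lower at −1.08, 31 of 32 not called), voltage-gated channels (Scn3b higher, Kcnc4 lower at −1.35, 53 of 55 not called), the integrated stress response (Herpud1 higher at 0.72, 43 of 44 not called), p53 response and apoptosis (Cdkn1a higher at 0.85, 35 of 36 not called), ribosomal proteins (Rpl7a lower at −0.67, 73 of 74 not called), and cholesterol synthesis, microglia and macrophage markers and clustered protocadherins with 0 called. Their adjusted p ran from 0.125 to 0.916. Fry called 10 lists.

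The second knockdown asked the same of cultures in which Tet2 was lower in every knockdown library. Of 16164 genes, 4180 were called, 2043 higher and 2137 lower, with 3938 of them called by edgeR (4243). The median size of the called changes was 0.67 on the log2 scale. Dhps rose from 256 ± 26.2 to 1223 ± 100.7 normalized counts (log2 fold change 2.26, SE 0.10, adjusted p 1.7e-11, n = 6 each), the intermediate filament gene Nes from 86.9 ± 10.9 to 522 ± 149 (2.54, SE 0.16) and the GTPase Ralb by 1.62 (SE 0.10). Acan rose by 2.32 (SE 0.22), the ubiquitin ligase Trim47 by 2.26 (SE 0.23), the orphan receptor Gpr3 by 2.22 (SE 0.26) and Arl2bp, which binds a ciliary GTPase, by 2.13 (SE 0.15). Zwint fell from 23476 ± 2166 to 2813 ± 335 (log2 fold change −3.06, SE 0.10, adjusted p 6.1e-14), and Slc25a22 from 3418 ± 312 to 417 ± 41.6 (−3.03, SE 0.10). The splicing factor Bud31 changed by −3.11 (SE 0.22), the surface protein Cd24a by −2.89 (SE 0.11), Igfbp3, which binds insulin-like growth factors, by −2.71 (SE 0.23), the redox regulator Txnip by −2.41 (SE 0.17), the transcription factor Camta1 by −2.32 (SE 0.13) and the GABA transaminase Abat by −2.01 (SE 0.10).

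Lists of activity-regulated, stress and cholesterol genes passed upwards in the second knockdown with the preset correlation. Of 32 immediate early genes 18 rose, 2 fell and 12 did not pass, with Fos from 401 ± 85.6 to 1826 ± 313 (log2 fold change 2.19, SE 0.14), Npas4 at 2.52, Nr4a1 at 1.76 and Trib1 at 1.50. The median was 0.57 and the list passed at an adjusted p of 1.2e-08 (0.123 with an estimated correlation), with 19 higher and 2 lower over the list alone. Of 44 genes of the integrated stress and unfolded protein response 24 rose (Mthfd2 1.68, Xbp1 1.10 and Trib3 1.58), 2 fell (Syvn1 −0.83 among them) and 18 did not pass, or 29 and 2 over the list alone (adjusted p 1.2e-08, but 0.123 with an estimated correlation). Of 25 genes of cholesterol synthesis 9 rose (Dhcr7 0.59 and Mvk 0.51) and 3 fell, or 10 and 3 over the list alone (adjusted p 0.0120, but 0.312 with an estimated correlation).

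Another 4 lists passed downwards there with the preset correlation, most of their members not being called. Of 67 genes of axon guidance and dendrite growth 3 rose and 24 fell (Stmn1 −1.19, Nfia −0.85, Sema7a −1.10 and Epha4 −0.69), or 3 and 26 over the list alone (adjusted p 9.9e-04, but 0.312 with an estimated correlation). Of 59 genes of cell adhesion at synapses 3 rose and 22 fell (Nlgn2 −1.46, Tenm3 −1.09, Negr1 −0.97 and Adgrl2 −1.27), or 3 and 25 over the list alone (adjusted p 0.00647, but 0.312 with an estimated correlation). Of 58 clustered protocadherins 0 rose and 10 fell (Pcdha5 −0.76 and Pcdhgc4 −0.69), or 0 and 7 over the list alone (adjusted p 0.00187, but 0.380 with an estimated correlation). Members of this cluster share exons, so their reads may be split between them. On this list shLuc 8 stood apart, with a mean log2 level of 5.91 against 6.26 to 6.45 in the other controls. Of 29 astrocyte markers 2 rose (Ttyh1 0.70) and 7 fell (Aldoc −0.82, Clu −0.67 and Cldn10 −0.80), or 3 and 10 over the list alone (adjusted p 0.0198, but 0.158 with an estimated correlation). Fry called 14 lists.

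The other 16 lists of the second knockdown did not pass as a whole (adjusted p 0.0519 to 0.965), and 14 of them held calls in both directions. In synaptic plasticity and memory 8 rose (Vgf 1.93, Nptx2 2.07 and Bdnf 1.28) and 11 fell (Cdk5r1 −1.07) of 50. Of 39 glutamate receptor genes 2 rose and 9 fell (Grin3a −1.77, Grm3 −1.07 and Gria3 −1.03), and of 38 GABA genes 8 rose (Dlx2 1.24 and Cck 0.66) and 9 fell. Synaptic vesicle genes (7 rose, 17 fell of 54, Cplx1 −0.75), voltage-gated channels (8 rose, 11 fell of 55, Scn3b 1.31, Kcnc4 −1.32) and neuropeptides (8 rose, 4 fell of 31, Crh 2.01) were similar. Hippocampal excitatory markers had 3 rises and 10 falls of 31 (Rfx3 −1.32), oligodendrocyte markers 1 and 4 of 27, vascular markers 2 and 7 of 27, proliferation genes 1 and 6 of 43, microglia markers 2 and 0 of 15 and interferon genes 4 and 5 of 44 (Cxcl10 −3.32). DNA methylation machinery had 3 rises and 9 falls of 32 (Idh2 −1.23), p53 and apoptosis genes 5 and 9 of 36 (Cdkn1a 0.92), ribosomal proteins 0 and 9 of 74 and the respiratory chain 5 and 5 of 73.

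The 2 knockdowns shared more calls in the same direction than independent lists would. Of 15796 genes tested in both, 239 were called in the same direction (53 higher and 186 lower, 46.0 expected) and 11 in opposite directions (45.4 expected). The count in the same direction was 84 without genes carrying the 3' UTR words CTGTACA or TCTGTAC and 150.0 with the replicate number of the first knockdown as a block. The correlation of fold changes across genes was 0.21, genes not being independent replicates. Dhps, Cmtm6, Nes, Scn3b, the phosphatase Dusp22 (1.29 in the first and 1.55 in the second), Diras2 and the microtubule severing gene Katnal1 (1.16 and 1.38) rose in both. Slc25a22, Bud31, Igfbp3, Zwint, the endosomal GTPase Rab5c (−1.67 and −1.69), Pyurf (−1.65 and −1.82) and the clock-controlled factor Hlf (−1.59 and −1.67) fell in both.

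**Figure D2:**
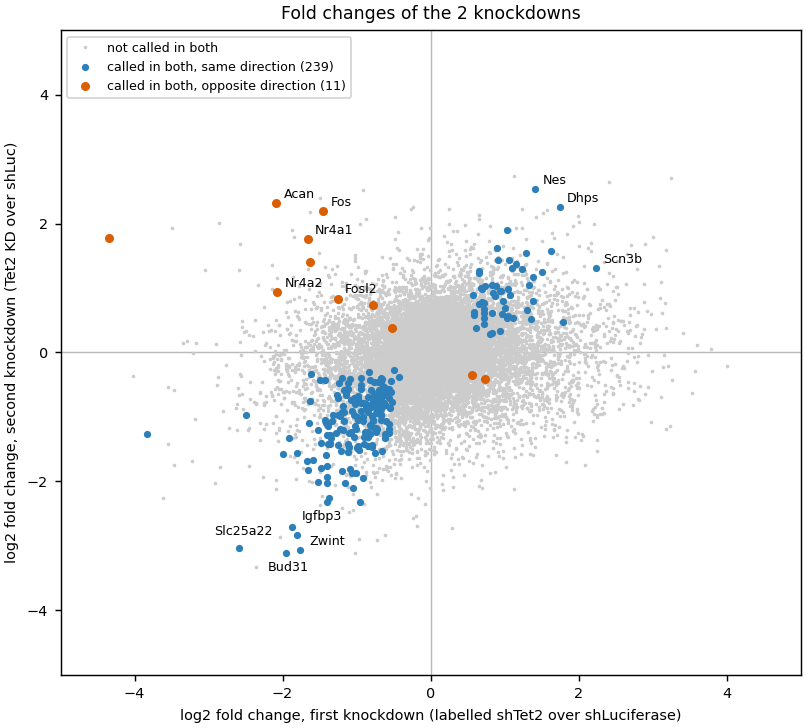
Each point is a gene, with its log2 fold change in the first knockdown (horizontal) and in the second (vertical). The 239 genes called in the same direction are blue, with 186 of them lower in both, and the 11 called in opposite directions are orange.

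As a list, immediate early genes went opposite ways in the 2 knockdowns (median −0.70 and 0.57), but not all members did. In the first, 27 of the 32 were not called. Fosl1, Ier2 and Trib1 were positive in both, and Jun, Dusp6, Btg2, Egr3 and Ptgs2 were negative in both. With an estimated correlation the list call of the second knockdown was lost (adjusted p 0.123). Fos, Nr4a1, Nr4a2, Nr4a3 and Fosl2, transcription factors induced by neuronal activity, fell in the first and rose in the second, as did Acan. A test of the difference itself called 289 of 15796 genes, 146 higher and 143 lower in the first knockdown relative to the second. Fos differed by −3.65 (SE 0.23, adjusted p 1.5e-11) and Nr4a1 by −3.42 (SE 0.25, adjusted p 2.8e-10) on the log2 scale. In the first knockdown Nr4a1 stood at 726 ± 99.8 in shLuciferase and 235 ± 63.2 in libraries labelled shTet2, and in the second at 190.4 ± 35.9 and 645 ± 106 (n = 6 each).

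**Figure D3:**
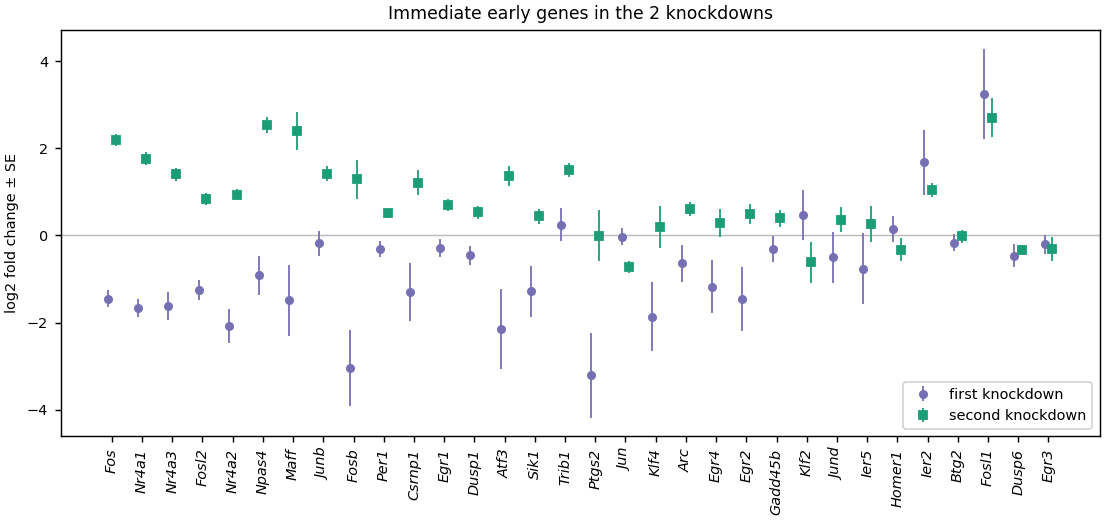
Log2 fold change with SE (vertical) of the 32 immediate early genes in the first (circles) and second (squares) knockdown, ordered by the p of their difference. Fos lies at −1.45 in the first and 2.19 in the second.

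A word in the 3' UTR was more frequent among genes that fell in either knockdown than among all genes searched. The 7-mer CTGTACA ranked first of 16108 downwards in the first knockdown and first of 16081 in the second. Its coefficients were −0.21 (SE over genes 0.015) and −0.35 (SE over genes 0.013) on the log2 scale. It lay in the 3' UTR of 111 of the 222 called and searched genes that were lower in the first knockdown and 683 of 1721 in the second (39.7%), against 16.9% and 16.5% of all genes searched. Slc25a22, Zwint, Cd24a, Igfbp3, Kit, Cend1, Bud31, Cplx1 and Camta1 carried it. In the nuclei its coefficient was −0.0067 (SE 0.017), and with overexpression it was 0.11 (SE 0.044). The 7-mer CTCTAGA ranked first upwards in both knockdowns (0.17, SE 0.019, and 0.20, SE 0.016) and lay in the 3' UTR of 41.8% of called genes that were higher in the first, among them Scn3b, Dhps, Diras2, Nrep and Cmtm6, and of 267 of 1777 in the second, against 11.1% and 10.9% of all genes searched. Every library labelled shTet2 or Tet2 knockdown had a lower CTGTACA score than every control library of its experiment.

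**Figure D4:**
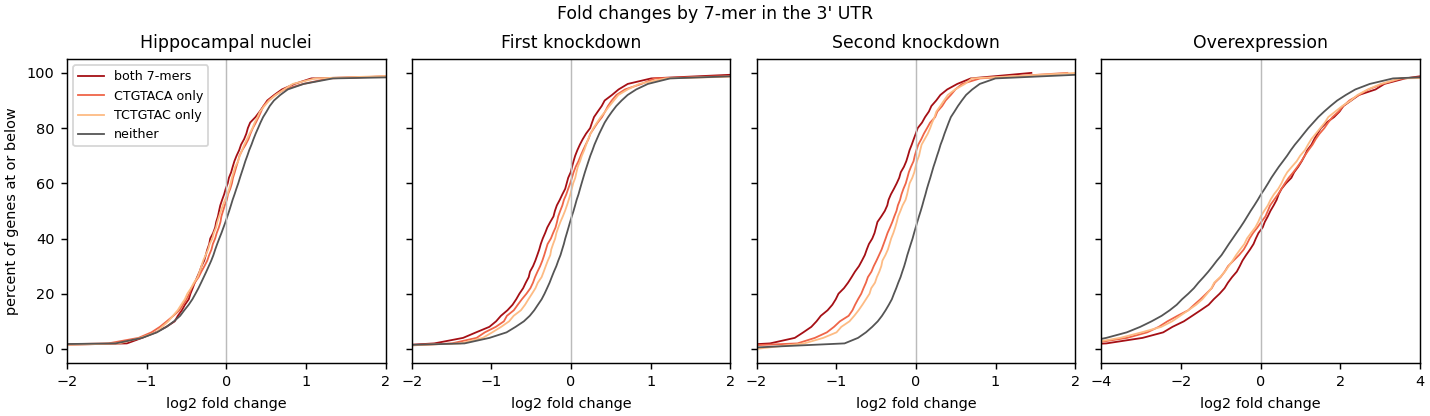
Percent of genes (vertical) at or below a log2 fold change (horizontal) for genes whose 3' UTR carries CTGTACA and TCTGTAC, only 1 of them, or neither, in each experiment. Genes with a site lie to the left of genes without in both knockdowns, where the matched median differences for CTGTACA are −0.22 and −0.32, and not with overexpression (0.086). In the nuclei CTGTACA genes also lie slightly to the left (median −0.065, against 0.028 without it), but not of matched genes (−4.8e-04).

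The overexpression experiment asked what more Tet2 changes in cultured neurons. Of 22399 genes 2230 were called, 1386 higher and 844 lower, 2029 of them also by edgeR (2266). The split moved with the scaling and with the genes kept. The median of all genes was −0.75 on the authors' size factors and −1.31 on library totals, where 861 were higher and 1802 lower. On the authors' size factors with the stricter filter, which drops more low genes, it was 0.061, with 2894 genes called. In edgeR, which kept 17696 genes, it was −0.55 with upper-quartile factors (1148 higher and 1198 lower) and −0.32 with RLE factors. After a correction for GC content and length it was −0.29 (1172 higher and 255 lower). The simulated recovery here was 11% for changes of 2, with far fewer genes changed in the simulation than were called. Called changes had a median size of 2.59. Without GFP 5 the count was 642, without GFP 4 it was 1482, and without Tet2 3, 4 or 6 it was 1443, 1254 or 1229.

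Called genes that rose with overexpression had longer transcripts than those that fell, with a median length of 4686 bases and a GC content of 45.9% against 2380.0 bases and 54.9%. The membrane protein gene Tmem170b rose from 3027 ± 528 to 195696 ± 59455 normalized counts (log2 fold change 5.98, SE 0.46, adjusted p 1.5e-06, n = 3 each), the insulin signalling adaptor Irs1 from 1055 ± 133 to 51608 ± 7773 (5.61, SE 0.41) and the phosphatase Ptp4a1 by 5.53 (SE 0.43). The cannabinoid receptor Cnr1 rose by 5.52 (SE 0.48), the glucocorticoid-induced Glcci1 by 5.38 (SE 0.43), the calcium channel subunit Cacna2d1 by 3.84 (SE 0.40) and the AMPA receptor subunit Gria1 by 3.12 (SE 0.42). Among the falls, the ribosomal protein gene Rps7 fell from 13362 ± 3470.0 to 1021 ± 287 (−3.71, SE 0.43, adjusted p 3.8e-05), the chaperonin gene Hspe1 changed by −3.13 (SE 0.43), the detoxification enzyme gene Gstp1 by −4.49 (SE 0.74) and Akt1s1, of the mTOR complex, by −4.17 (SE 0.74). Amd1 (12.05), whose near-identical paralog may share reads, Pcdha7 (−5.36) and the rRNA-like Rn45s (−4.05) and Lars2 (−4.48) remain uncertain, and Amd1 and Pcdha7 were not called by edgeR (adjusted p 0.0801 and 0.344).

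With overexpression 5 lists passed with the preset correlation, the ribosomal and respiratory lists downwards. Of 74 cytosolic ribosomal protein genes 0 rose, 54 fell (Rps7, Rps12 −3.20 and Rplp1 −3.13) and 20 did not pass, with 62 lower over the list alone. Their median was −2.32, against −0.75 for all genes that passed the main filter. The list passed at an adjusted p of 3.0e-27 (0.338 with an estimated correlation). Ribosomal protein genes took 0.443% to 0.646% of the reads in Tet2 and 2.64% to 4.05% in GFP libraries. Of 72 respiratory chain genes 0 rose and 23 fell (Cox7c −3.12, Uqcrc1 −2.49, Cox6b1 −2.21 and Cox7a2 −2.24), or 36 over the list alone (adjusted p 1.4e-08, but 0.338 with an estimated correlation). Of 59 genes of cell adhesion at synapses 18 rose (Negr1 3.64, Slitrk2 3.54 and Opcml 3.44) and 3 fell, or 22 and 7 over the list alone (median 0.74, adjusted p 6.9e-06, but 0.338 with an estimated correlation). GABA genes had 8 rises (Gabra2 2.79) and 3 falls (Cck −3.33) of 38, and voltage-gated channels 11 rises (Kcna1 2.95 and Kcnc2 3.02) and 2 falls of 55. Both passed upwards at an adjusted p of 0.0379, with medians of 0.16 and 0.22 but means of −0.0083 and −0.17, and both calls were lost with an estimated correlation (adjusted p 0.352 and 0.338). Fry called 6 lists.

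The other 18 lists did not pass with overexpression (adjusted p 0.166 to 0.897). Among them were axon guidance with 14 rises and 3 falls of 67 (Plxna2 2.81, Map1b 4.20), synaptic vesicle genes with 10 and 6 of 54 (Pclo 2.35, Cplx1 −2.51), plasticity genes with 9 and 4 of 50 (Pde4d 2.68, Camk4 2.52), glutamate receptors with 4 and 1 of 39 (Gria3 2.57, Gria2 2.24) and DNA methylation machinery with 4 and 1 of 32 (Ogt 2.55). Immediate early genes had 2 rises and 5 falls of 32 (Btg2 2.05, Jund −4.11), neuropeptides 1 and 3 of 30 (Pcsk2 2.36, Sst −3.79, Vgf −4.70), protocadherins 4 and 6 of 58 and the stress response 4 and 4 of 44 (Vldlr 3.32, Calr −2.09). Of 29 astrocyte markers 4 rose (Aqp4 3.31) and 1 fell (Fabp7 −2.13), and of 33 oligodendrocyte markers 1 rose and 3 fell (Olig1 −3.63). Microglia markers had 0 rises and 1 fall of 31, vascular markers 1 and 1 of 33, hippocampal excitatory markers 2 and 3 of 32 and proliferation genes 3 and 4 of 43.

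**Figure D5:**
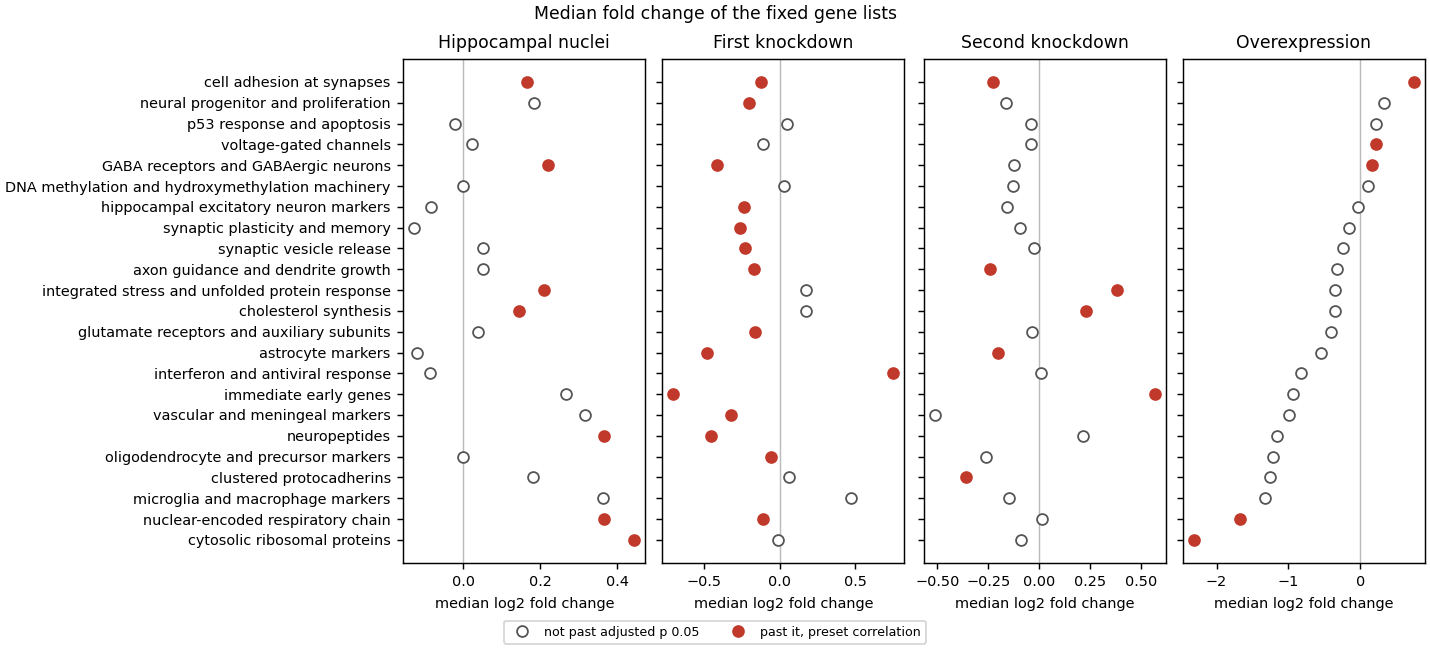
Median log2 fold change of each fixed gene list in the 4 experiments, filled where the list passed an adjusted p of 0.05 with the preset correlation. The ribosomal list lies at 0.44 in the nuclei and −2.32 with overexpression, and only the immediate early list of the first knockdown also passed with an estimated correlation.

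Loss and gain were compared between experiments, none of which shared libraries. Between the second knockdown and overexpression 474 genes were called in opposite directions (272 expected) and 206 in the same (268 expected), of 16079 tested in both. The matrix receptor gene Dcbld2 (−1.70 and 2.32), Ptchd1 (−1.80 and 3.77), Cdv3 (−1.95 and 3.17) and Hlf (−1.67 and 1.69) were lower with knockdown and higher with overexpression, and the glycan enzyme gene B3gat3 (1.68 and −1.48, the latter of the other sign and not called after correction for GC content and length) went the other way. After the correction for GC content and length the counts were 232 opposite (176 expected) and 213 same (198 expected), and the correlation went from −0.12 to −0.034. Slc25a22 was lower in all 3 culture experiments (−3.02 with overexpression). Between the first knockdown and overexpression 39 genes were called in the same direction (19.1 expected, Katnal1 and Bivm among them) and 20 in opposite directions (22.8 expected). The nuclei shared 0 called genes with either knockdown, having 0 calls. At an unadjusted p under 0.01, 11 genes went the same way as in the first knockdown (8.80 expected) and 20 the opposite way (8.40 expected), with a correlation of −0.14 across genes. With the second, 40 went the same (37.4 expected) and 41 the opposite way (36.9 expected), with a correlation of 0.029.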

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

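The tests of difference between the knockdowns were planned before the data were examined, while the tests of explanations for the immediate early genes were chosen after that result was seen.

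The list of immediate early genes moved in opposite directions in the 2 knockdowns, though not all of its members did. Fos, Nr4a1, Nr4a2, Nr4a3 and Fosl2 were called lower in the first and higher in the second. Fosl1 and Ier2, in contrast, were positive in both, and Jun and Dusp6 negative in both. A test of the difference between the fold changes called 289 of 15796 genes. Of 100 drawn pairs of splits 2 gave as many, the real one included (highest other 291), a share under 0.05. These splits redrew the groups within both experiments, so they stand for no treatment effect in either. Whether the 2 effects were equal cannot be decided by them, and no conclusion on the difference is drawn from them. On the log2 scale the first knockdown minus the second was −3.65 for Fos, −3.42 for Nr4a1, −3.03 for Nr4a3 and −2.08 for Fosl2. In the other direction it was 1.30 for Zwint and 1.92 for Cd24a, whose changes were negative in both but smaller in the first, 1.40 for Camk2n1, an inhibitor of the kinase CaMKII, and 0.91 for Fxyd6, a regulator of the sodium pump. The list of immediate early genes differed at an adjusted p of 4.8e-20, and of 1.1e-04 with an estimated correlation. Another 8 lists differed with the preset correlation only: neuropeptides (8.0e-08), the integrated stress response (3.3e-04), the respiratory chain (6.8e-04), interferon genes (0.00392), synaptic plasticity (0.0156), GABA genes (0.0240), synaptic vesicle genes (0.0366) and astrocyte markers (0.0389). With an estimated correlation the adjusted p of these 8 ran from 0.136 to 0.871.

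CTGTACA or TCTGTAC sites in the immediate early genes themselves were excluded as the whole cause of their opposite changes with the preset correlation. Of the 32, 7 carry such a site, and without site genes the list still passed in both knockdowns (larger adjusted p 1.8e-10). Genes with only GCTGTAC, ACTGTAC or CTCTAGA were kept, Fosl2 with CTCTAGA among them. Other sites, and changes that follow from off-target falls of other genes, were not tested. An outlying library was excluded as well, since the list passed in the same direction without each library in turn (largest adjusted p 1.1e-07, also with the preset correlation). With an estimated correlation the list did not pass in the second knockdown even with all genes and libraries (adjusted p 0.123), so these tests rest on the preset one. A different state of the cultures may be the cause, as the control libraries of the first knockdown held more of these transcripts (median difference 1.52 in log2 CPM). This cannot be told apart from other differences between the experiments, because cultures, RNA extraction and control libraries change together. The column names of the second knockdown also carry a mark that those of the first lack. A lower Tet2 transcript was not seen in the first knockdown, though the 95% confidence interval of its log2 fold change (−0.39 to 0.80) does not exclude a small decrease. Whether a lower transcript contributed to the rise in the second stays open and was not tested.

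In 5 of the 76 groups of libraries and measures examined, 1 library lay far from the rest of its group, where about 3.8 are due to chance. The mean log2 level of cell adhesion genes was 9.78 in WT nuclei 6, with 9.87 to 9.88 in the others. In shLuciferase 4 of the first knockdown synaptic vesicle genes stood at 9.30 (others 9.46 to 9.55) and interferon genes at 2.51 (others 3.12 to 3.48). Neuropeptides stood at 8.89 in shLuciferase 2 (others 8.02 to 8.29), and clustered protocadherins at 5.91 in shLuc 8 of the second knockdown (others 6.26 to 6.45).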

How the results depend on the processing

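Of the values of the main results under alternatives, 246 kept their direction and their side of the threshold, or stayed within 1.5 times for a count, 48 moved and 2 reversed. The scalings by TMM factors and library totals, the correction for GC content and length, the sets of libraries or columns, the removal of site genes and the separate standard errors were chosen after seeing the data. Unless a construction with fewer genes or libraries is named, the cause was not tested. In the nuclei DESeq2 called 91 genes and the authors' adjusted p 96, against 0, and 12 lists passed after the GC and length correction, but 0 with an estimated correlation and 0 with fry, against 7. In the first knockdown, against 354 genes, DESeq2 called 888, voom 900.0, the authors' adjusted p 846 and the fit without site genes, which has fewer genes, 141. Leaving out 1 library gave 222 (without shLuciferase 3) to 354, with 234 without shTet2 4. The log2 fold change of Tet2 there was −0.11 with voom and −0.059 (without shLuciferase 2) to 0.36 with 1 library left out, and with an estimated correlation 1 list passed, against 15. Without the 3 libraries that lay apart on the principal components 349 genes were called. In the second knockdown, against 4180 genes, columns 1 to 6 alone gave 1149 and columns 7 to 12 alone 2655, with fewer libraries, and 0 lists passed with an estimated correlation and 14 with fry, against 7. With overexpression, against 2230 genes, DESeq2 called 4084, voom 4049, the authors' adjusted p 4057 and the GC and length correction 1427. Leaving out 1 library gave 642 (GFP 5) to 3004 (GFP 6), with 1482 without GFP 4 and 1443, 1254 and 1229 without Tet2 3, 4 and 6. Lists passing there, 5 with all libraries, numbered 3 with upper-quartile factors, 3 with the stricter filter, 3 with library totals, 0 with an estimated correlation and 3 to 7 with 1 library left out. Tet1, not called with overexpression, reversed to −0.13 with upper-quartile factors, −0.53 with library totals, −0.40 with the GC and length correction and −0.25 (without GFP 4) to 0.46 (without GFP 6) with 1 library left out, and B3gat3 reversed to 0.67 with that correction. The 239 genes shared by the knockdowns became 371 at an adjusted threshold of 0.1, 492 at an unadjusted 0.01 and 84 without site genes. The 474 opposite in the second knockdown and overexpression became 844 at 0.1 and 232 after the GC and length correction, and the 20 opposite in the first knockdown and overexpression became 36 with the stricter filter, 58 at 0.1 and 87 at 0.01. The nuclei shared 31 genes with the first and 81 with the second knockdown at 0.01, against 0. The 289 genes that differed between the knockdowns became 590.0 at 0.1, 1015 at 0.01, 189 without site genes and 654 with each table's own standard error. Of the values of single genes, 262 of 1991 lost their call in the first knockdown, 49 of 3338 in the second and 312 of 2122 with overexpression.

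Samples of the first knockdown share replicate numbers with no stated meaning. With the replicate number as a block 206 genes were called, the knockdowns shared 150.0 and differed in 465, and 15 lists passed as before. Libraries of equal number did not deviate together (correlations −0.144 to 0.0457 over 6 pairs, 0 of 6 best with their own number), so the numbers do not pair them. No paired analysis was possible because the mice of the nuclei groups share no number, and the columns of the second knockdown and overexpression tables carry other numbers than the sample titles.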

Other observations

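The tests of the 3' UTR word and of the ribosomal and respiratory genes were chosen only after those results were seen, and the other splits of the libraries were planned before the data were examined.

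Genes with CTGTACA in the 3' UTR were lower in both knockdowns, including the first, where the Tet2 transcript was not. A lower Tet2 transcript level was not seen to go with the fall. The coefficient was −0.21 (SE 0.015) in the first knockdown, where the transcript was not measurably lower. It was −0.0067 (SE 0.017) in the nuclei, where Tet2 was lower but not past the threshold (adjusted p 0.632). The 95% confidence interval of the Tet2 fold change in the first knockdown (−0.39 to 0.80) leaves room for a small decrease, so this cause was not excluded. Tet2 protein was not measured, so a lower protein level stays open as well. The GC content and length of the 3' UTR were excluded, as site genes lay below matched genes in both knockdowns (upper 95% limit over genes of the nearer median difference −0.198). So was a mislabelled library, since 0 of the 6 libraries labelled shTet2 had a site score among those of shLuciferase. The word was picked on these same labels, which favours a separation of the groups, but it also ranked 1 in the separate libraries of the second knockdown. Off-target pairing of the Tet2 hairpin, like that of a microRNA seed, may be the cause: the word ranked 1 downwards in the first knockdown ranked 1 among 16081 in the second, and site genes did not lie below matched genes where no hairpin was used (−4.8e-04 in the nuclei and 0.086 with overexpression). The transcript Tet2-201 (9179 bases) carries the extended word TCTGTACA 2 times, as 139 of 681 coding transcripts of similar length (20.4%) do at least 1 time, but the hairpin sequences are not in the labels.

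This limits what the knockdowns say of Tet2. Site genes such as Slc25a22, Zwint and Bud31 could have fallen without a change in the Tet2 transcript. Without genes carrying CTGTACA or TCTGTAC, 141 genes (70.0 higher and 71 lower) of the first knockdown were called. In the second, 2855 were called (1773 higher and 1082 lower). The same doubt holds for these genes, as those carrying only GCTGTAC, ACTGTAC or CTCTAGA were kept. GCTGTAC and ACTGTAC ranked 4 and 3 downwards in the first knockdown and 3 and 4 in the second. In the first, moreover, Tet2 was not lower. The word CTCTAGA, first upwards in both knockdowns, had scores of −0.114 to −0.0395 in shLuciferase and 0.0693 to 0.120 in libraries labelled shTet2. Whether it marks sites of the luciferase hairpin was not tested.

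With overexpression short transcripts of ribosomal and respiratory genes were lower. For the ribosomal list GC content and transcript length were excluded as the whole cause. After their correction it passed (adjusted p 1.4e-12), with 22 genes lower, against 54, and a median of −1.37, from −2.32. Its mean relative to all genes was −0.90 (95% interval over libraries −1.71 to −0.10), from −1.43. A difference in depth was excluded by thinning every library to 16988077 reads (adjusted p 1.5e-30, with 2370.0 genes called, 2074 of them shared), and 1 outlying library by leaving out each in turn (largest adjusted p 2.5e-17). A difference in library preparation that follows the groups may remain and was not tested, as 3 libraries against 3 give no other batch. Fewer genes had a read in the deeper Tet2 libraries (16457 to 18371) than in the GFP libraries (18540 to 21194), and thinning does not address this. Rn45s also differed between the groups (0.0607% to 0.411% of the reads in GFP, 0.00452% to 0.00662% in Tet2 libraries), and the list call was lost with an estimated correlation (adjusted p 0.338), while an effect of Tet2 itself stays open.

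For the respiratory list, GC content and transcript length cannot be told apart from other causes: after their correction it passed (adjusted p 0.0165) with 4 genes lower, against 23, but its mean relative to all genes went from −0.77 (95% interval −1.30 to −0.23) to −0.32 (−0.73 to 0.093). Depth was excluded there by thinning (adjusted p 3.5e-09), and 1 outlying library by leaving out each in turn (largest adjusted p 2.5e-06). The call of this list was also lost with an estimated correlation (adjusted p 0.338).

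Other splits of the libraries were set against the main counts. For the genes of the first knockdown 1 of 100 splits, the real one, gave as many, so chance can be excluded (354, highest other 1). The same holds for the genes of the second knockdown (1 of 100, with 4180 and highest other 1997). For the lists of the first knockdown 1 of 100 splits, the real one, gave as many as 15, a share under 0.05, but another gave 14. No conclusion on these lists is drawn from that count, as only 1 of the 15 held with an estimated correlation. Chance could not be excluded for the lists of the second knockdown (32 of 100; 7, highest other 14) or of the nuclei (10 of 35; 7, highest other 9).

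Some splits could not test chance, because their outcome was fixed. Other splits called too few genes to share as many as the knockdowns did with each other (1 of 100; 239, highest other 0) or as went opposite in the second knockdown and overexpression (1 of 100; 474, highest other 0). For the genes of the nuclei (35 of 35; 0, highest other 2) and those they shared with the second knockdown (100 of 100; 0, highest other 0) the real count was 0. For overexpression 10 splits are too few for a share under 0.05 (genes 2230, highest other 2, with 1 split as large; lists 5, highest other 8, with 4).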
